A study of Mus musculus with 4 samples.

How the data were processed

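The series holds 4 RNA-seq libraries of OG2ES, a mouse embryonic stem cell line, grown in mouse ES cell medium with 2i, the inhibitor pair that holds such cells in the naive state. Per the labels, 2 libraries came from wild-type (WT) cells and 2 from cells deficient in Myh9 (Myh9 KO). Total RNA was extracted with TRIzol, mRNA was enriched on oligo-dT beads and cDNA was primed with random hexamers, per the labels' protocols. These describe no step that marks the RNA strand, so reads of overlapping genes on opposite strands cannot be told apart. The labels do not say that the replicates were separate cultures, so every p-value of a single gene here measures the spread between these libraries, which may be technical. The p-values of gene lists and chromosomes rest also on the spread between genes, as described below.

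The deposited table held 50600 gene rows with coordinates, an Ensembl identifier, a name and a value for each library. The deposited values were treated as a score: they were whole numbers that summed to 992128, 992098, 992245 and 992317 in WT 1, WT 2, Myh9 KO 1 and Myh9 KO 2, nearly equal totals such as per-million values give once their decimals are dropped. They were therefore not treated as read counts, the depth of each library is unknown, and whether the decimals were rounded or removed is not stated. Bowtie2 2.2.5, RSEM 1.3.0 and bcl2fastq were named without a role, per the submitters' processing notes, together with the builds mm10 and hg38. Of the 50600 identifiers, 50376 were found in the GENCODE vM21 annotation of GRCm38 (mm10), and 92.91% of those had the same coordinates, so coordinates are given on mm10. Of 27 gene names turned into dates in the table, 26 were restored from their identifiers.

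Because the values were not counts, the design's test for normalized values was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), for genes with a mean value of at least 1 over the 4 libraries, Myh9 KO against WT with no replicate block, and Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Standard errors (SE) and 95% confidence intervals come from the same fit, with n = 2 libraries per group throughout. Genes listed at 0 in a group are given as values with no fold. Mki67, Rock1 and Rock2 were listed at 0 in every library, so a 0 can be a failed estimate.

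The fit was tested on simulated values for the 11231 tested genes, drawn from the real means and the replicate spread and reduced to whole numbers. The simulated spread depended on expression level only and was independent between genes, with no trend on GC content. False calls in the real data may therefore be more frequent than in the simulations. With 2000 genes changed, 48.6%, 75.0% and 96.7% of those changed 1.5-fold, 2-fold and 4-fold were called, and 13.9% of 1705 calls were unchanged genes. These lay mostly among genes whose replicates had equal whole numbers in both groups (41.2% of 519 such calls, against 1.94% of the other 1186), since equal replicates leave no spread. With 200 genes changed, 62.4% of 287 calls were unchanged genes. A second fit was therefore added after the data were seen, in which a uniform number between 0 and 1 was added to every value before the log and each gene's adjusted p was the median over 25 draws (called random decimals below). In the same simulations 2.40% of its 1879 calls and 0.552% of its 181 calls were unchanged genes. Counts are given for the designed test and, where they differ, for the calls made by both tests. A gene is written as having risen or fallen only where both tests called it in that direction; of genes called by both in the simulation with 2000 changes, 0.498% were unchanged.

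The design fixed 31 gene lists and the rule for named genes before the data were examined. Named genes were Myh9, the 10 largest rises and 10 largest falls among called genes with a mean value of at least 2 and no overlap between groups, leaving out unnamed predicted genes and pseudogenes. To these came up to 4 called members of each list with the smallest p (up to 2 members where none was called), and 10 genes named in every case, such as Pou5f1, Sox2, Nanog, Klf4, Cdh1, Myh10 and Myh14. A gene that this rule names is not reported here. Other genes named in the text are members of those lists or are said to have been chosen after their values were seen. For each list the number of called members is given over all genes tested and adjusted over the list alone. The 29 lists with at least 5 tested members were tested with camera in limma with a preset correlation of 0.01, adjusted over the 29 lists. They were tested again with an estimated correlation and with fry. With the preset correlation camera takes its degrees of freedom from the number of genes. Its p-value then rests on the spread between genes and on the assumed correlation, not only on the spread between libraries. It is too small for a list whose genes vary together more than assumed. With an estimated correlation camera takes its degrees of freedom from the 4 libraries, so few lists can pass and a failure there alone decides little. In a simulation of 20 lists, camera called both changed lists and 0 of 18 unchanged lists. Its genes varied independently, so it does not show how camera behaves for lists of correlated genes.

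GC content and transcript length were taken from the GENCODE vM21 transcripts. The share of each named gene's 50-base words that also occur in transcripts of other genes, on either strand, was computed in Python 3.11.15 as a measure of reads that can be split between copies. Figures were drawn with matplotlib 3.10.9. Alternatives covered the pseudocount (0.1 and 5), the filter on low values, the replicate number as a block, each library left out in turn, a tested minimum change of 1.5-fold, an adjusted p under 0.01 and the other list tests. Added after the data were seen were random decimals, also with each library left out, 2 other scalings, removal of a trend on GC content and transcript length, and the fit without genes of chromosomes 6 and 8. The planned tests that need read counts were not run.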

Results

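Gene expression was measured by RNA-seq in mouse embryonic stem cells of the OG2ES line, in 2 WT and 2 Myh9 KO libraries from cells kept in medium with 2i. The single comparison asks how the transcriptome differed between Myh9 KO and WT cells, in a study of altered colony morphology and its relation to pluripotency. With a single Myh9 KO group, a difference particular to the KO line or clone cannot be told apart from an effect of the loss of Myh9. This holds for every result below. Between 11653 and 11947 genes had a value above 0 in a library, and 11231 genes were tested. Across tested genes, Pearson's r was 0.991 between the WT libraries, 0.988 between the Myh9 KO libraries and 0.964 to 0.968 between groups. The first principal component held 73.4% of the variance.

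Myh9, the heavy chain of non-muscle myosin IIA and the targeted gene (ENSMUSG00000022443, mm10 chromosome 15, 77760587 to 77842175), fell in Myh9 KO cells. Its values were 83 and 100 in WT 1 and WT 2 and 9 in each Myh9 KO library, a log2 fold change of -3.20 (SE 0.12, limma adjusted p = 0.00675). The transcript was thus lower but still listed in both libraries. Myh14, the heavy chain of non-muscle myosin IIC, rose from a value of 2 in each WT library to 5 and 6 (log2 fold change 1.11, SE 0.10, adjusted p = 0.0277). Myh10, the heavy chain of non-muscle myosin IIB, had values of 13 and 17 in WT and 14 and 11 in Myh9 KO (log2 fold change -0.24, SE 0.21, adjusted p = 0.489), with a 95% confidence interval of the fold from 0.505 to 1.41. Leaving out Myh9 KO 1 or Myh9 KO 2 raised the adjusted p of Myh9 to 0.069 and 0.0724 at the same fold. With random decimals it stayed at or below 5.25e-05 with any library left out.

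**Figure D1:**
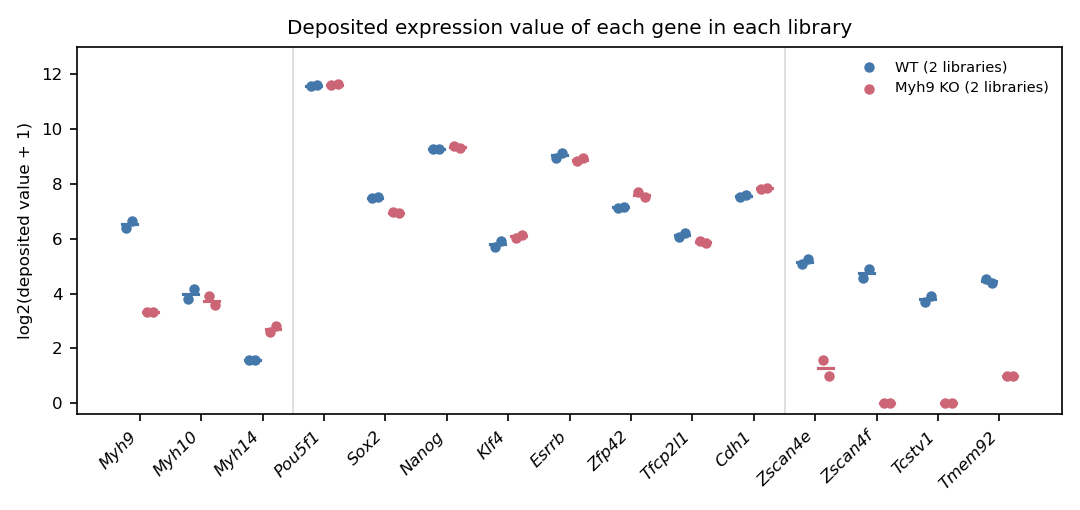
Deposited value of each gene in each library, on the log2(value + 1) scale. Points are the 2 libraries of WT and of Myh9 KO and short lines are their means. Myh9 lay at 83 and 100 in WT and at 9 in each Myh9 KO library, and the 4 genes of the 2-cell-like list on the right lay at 0 to 2 in Myh9 KO.

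Of 11231 genes tested, 805 were higher and 894 lower in Myh9 KO by the designed test, and 575 and 648 of these were also called with random decimals, which alone called 1242 and 1345. Those counts were 611 and 642 without WT 1 and 716 and 611 without WT 2. Calls of at least 2-fold numbered 120 higher and 237 lower by both tests. Slc16a3, a lactate exporter, had the largest rise among genes detected in every library, from 10 and 9 to 77 and 68 (log2 fold change 2.81, SE 0.10, adjusted p = 0.00637). Hal, Mt4 and Thpo were listed at 0 in both WT libraries and had values of 8 and 6, 4 and 6, and 5 and 3 in Myh9 KO. The other large rises were those of Aire (3 and 3 to 17 and 17), Mt3 (1 and 1 to 8 and 8), Pou2f3 (3 and 4 to 18 and 18), Atp1b2 (10 and 11 to 45 and 46), Evc (1 and 1 to 7 and 6) and Pianp (6 and 6 to 26 and 24). Aire overlaps Dnmt3l, and Evc overlaps Crmp1, so reads may have been split between these neighbours.

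The largest falls were dominated by genes of the 2-cell-like state, a rare state of mouse ES cells that resembles the cleavage-stage embryo. Zscan4f (23 and 29), Tcstv3 (12 and 19), Tcstv1 (12 and 14), Zscan4b (12 and 12) and Zscan4c (10 and 12) were listed at 0 in both Myh9 KO libraries. Zscan4e fell from 33 and 37 to 2 and 1, and Tmem92 from 22 and 20 to 1 and 1 (log2 fold change -3.46, SE 0.06, adjusted p = 0.00182). Outside this list, D13Ertd608e went from 14 and 15 to a listed 0 in both Myh9 KO libraries, and H2-Eb1, an MHC class II chain, fell from 27 and 26 to 1 and 1. Erdr1, listed on chromosome Y, fell from 210 and 193 to 13 and 17. Of the 50-base words of D13Ertd608e and Erdr1, 89.6% and 40.5% occur in other genes, which makes their single-gene values uncertain.

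Among the main transcription factors of pluripotency, Pou5f1, Nanog and Esrrb were called by neither test and Sox2 fell. Pou5f1, the gene of Oct4, had values of 3045 and 3122 in WT and 3104 and 3189 in Myh9 KO (log2 fold change 0.03, SE 0.02, limma adjusted p = 0.489), and the 95% confidence interval of its fold ran from 0.962 to 1.08. Nanog had values of 616 and 622 and of 664 and 641 (fold interval 0.994 to 1.12, adjusted p = 0.174), and Esrrb values of 498 and 555 and of 461 and 488 (fold interval 0.748 to 1.09, adjusted p = 0.326). Sox2 fell from 177 and 183 to 126 and 121 (log2 fold change -0.54, SE 0.03, adjusted p = 0.0178). Klf4 (51 and 59, then 65 and 69), Zfp42 (140 and 142, then 210 and 181), Tfcp2l1 (66 and 73, then 59 and 57) and Cdh1, the gene of E-cadherin (181 and 192, then 226 and 232), were not called by the designed test, with adjusted p of 0.187, 0.0951, 0.133 and 0.0553. With random decimals these 4 genes passed, at adjusted p of 0.049, 0.00332, 0.0449 and 0.0063, with log2 fold changes between -0.26 and 0.46 in the designed test.

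Of 18 members of the core pluripotency list, 2 rose and 4 fell (2 and 7 adjusted over the list alone). Lin28a, which codes for an RNA-binding protein, rose from 111 and 114 to 215 and 217 (log2 fold change 0.94, SE 0.02, adjusted p = 0.00274), and Gdf3 rose from 198 and 200 to 255 and 262. Dppa5a fell from 4755 and 4841 to 3438 and 3205 and Fbxo15 from 92 and 105 to 54 and 50. Of 20 naive pluripotency genes, 3 fell and 17 were not called (1 higher and 3 lower adjusted over the list alone). These were Nr0b1 (log2 fold change -0.83, SE 0.03), Tcl1 (-0.58, SE 0.02) and Dppa3 (-1.28, SE 0.07), the last also known as Stella. Of 15 formative and primed genes, Dnmt3l (320 and 336 to 618 and 620) and Etv4 (79 and 84 to 114 and 125) rose, and 1 was higher adjusted over the list alone. The primed marker Fgf5 was listed at 0 in all 4 libraries. So were Mki67, Rock1 and Rock2, which dividing cells use, so a listed 0 does not show that a transcript was absent. No pluripotency list passed camera, with adjusted p of 0.504 for the core, 0.504 for the naive and 0.258 for the primed list. By fry, which does not compare a list with other genes, the core list was lower (adjusted p = 0.0104). The naive and primed lists did not pass fry (adjusted p = 0.0619 and 0.455). With random decimals 2 of the 18 core members were higher and 7 lower.

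In the 2-cell-like list, 16 of 17 tested members fell (17 adjusted over the list alone) and 15 were listed at 0 in both Myh9 KO libraries. The member not called was Duxf3, at 5 and 2 in WT and listed at 0 in Myh9 KO. Usp17le (7 and 7) and Usp17ld (2 and 2) were likewise listed at 0 in Myh9 KO. The list was lower by camera with the preset correlation (adjusted p = 1.82e-12). With an estimated correlation, where few lists can pass, camera gave an adjusted p of 0.50. Of the 50-base words of Zscan4b, Zscan4c, Zscan4e and Zscan4f, 85.5% to 90.1% occur in other genes, so their single-gene values are uncertain. The sum over the 9 Zscan4 rows went from 102 and 116 in WT to 2 and 1. Of 5 tested germline genes 3 fell (4 adjusted over the list alone), namely Rpl10l, a ribosomal protein paralog (148 and 162 to 51 and 49), Mael (5 and 6 to 2 and 2) and Dazl (2 and 2 to a listed 0). The germline list was lower by camera (adjusted p = 0.00268; adjusted p = 0.70 with an estimated correlation), and most of its members were below the filter.

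Of 16 tested trophoblast genes 5 were higher (6 adjusted over the list alone), 4 of them by both tests. Eomes, a T-box factor, rose from 6 and 6 to 11 and 11 and Esx1 from 4 and 4 to 7 and 7. Krt18 rose from 23 and 20 to 35 and 37 and the imprinted Peg10 from 23 and 23 to 49 and 51. Cdx2, the trophectoderm regulator, had values of 6 and 6 and of 7 and 7 and was not called with random decimals, while Elf5, Krt7 and Hand1 were listed at 0 in every library. The trophoblast list was higher by camera (adjusted p = 0.000593; adjusted p = 0.50 with an estimated correlation).

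Of 10 tested genes of primitive and definitive endoderm, 3 were higher and 1 lower (5 and 1 adjusted over the list alone). The basement membrane collagen gene Col4a1 rose from 12 and 11 to 24 and 24, Hnf4a went from a listed 0 to 2 and 3, and Sparc fell from 214 and 212 to 155 and 162. Cxcr4 had values of 1 and 1 and of 2 and 2 and was not called with random decimals. Gata6, Sox17, Sox7 and Foxa2 were listed at 0 in both WT libraries and at 0 or 1 in Myh9 KO. The list was higher by camera (adjusted p = 0.0389; adjusted p = 0.70 with an estimated correlation). This was lost without Myh9 KO 1 (0.058), without Myh9 KO 2 (0.27) and without genes of chromosomes 6 and 8 (0.096). Of 8 mesoderm genes, Eomes and Twist1 (1 and 1 to 3 and 4) rose (2 adjusted over the list alone, camera adjusted p = 0.158, and 0.046 without Myh9 KO 1). Of 6 tested ectoderm and neural genes limma called 0, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 and a camera adjusted p of 0.399. Tubb3 had values of 100 and 101 and of 89 and 85, Nes of 2 and 3 and of 1 and 1, and Pax6 was listed at 0 throughout. Of 16 feeder fibroblast markers only Thy1, Pdgfrb and Fstl1 reached the filter, and Fstl1 fell from 50 and 52 to 35 and 34 (1 adjusted over the list alone). Of 8 tested genes of epithelial-mesenchymal transition, Tgfbi (listed at 0 in WT, 2 and 2 in Myh9 KO) and Mmp2 (4 and 4 to 8 and 9) rose (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.173).

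Among 20 partners and regulators of non-muscle myosin II, 1 rose and 3 fell (3 and 7 adjusted over the list alone). Besides Myh14, these were the small GTPase gene Rhoa (497 and 482 to 395 and 390, log2 fold change -0.32, SE 0.02, limma adjusted p = 0.0201), the regulatory light chain gene Myl12a (468 and 438 to 329 and 330, log2 fold change -0.46) and the phosphatase subunit gene Ppp1cb (46 and 49 to 35 and 33, log2 fold change -0.47). Over the tested members of this list, log2 fold changes ran from -1.52, in a member that was not called, to 1.11. Rhoa and Ppp1cb have a GC content of 45.1% and 42.0%, and genes of 31.9% to 46.4% GC had a median log2 fold change of -0.19. For Myl12a (50.4% GC) the median of genes of 50% to 53.3% GC was -0.01. Of 18 targets of MRTF and SRF, factors that respond to the actin pool, 3 rose and 3 fell (4 and 4 adjusted over the list alone). Cytoplasmic actin moved both ways, with Actg1 down from 2884 and 2888 to 2192 and 2247 and Actb up from 3993 and 3988 to 4565 and 4767. Of the 50-base words of Actg1 and Actb, 37.4% and 9.12% occur in other genes. The focal adhesion gene Zyx rose from 17 and 18 to 32 and 36, Tagln2 rose, and Cnn2 and Wdr1 fell. Of 17 YAP and TEAD targets 1 was higher and 4 lower (1 and 5 adjusted over the list alone), 3 of them lower by both tests. These were Cyr61 (50 and 53 to 24 and 27, log2 fold change -0.99), Ctgf (41 and 45 to 21 and 22, log2 fold change -0.97) and Amotl2 (80 and 88 to 52 and 55, log2 fold change -0.64). Lats2 (3 and 3, then 2 and 2) and Arhgef17 (6 and 6, then 7 and 7) were not called with random decimals. None of these 3 lists passed camera, with adjusted p of 0.504, 0.504 and 0.178. The YAP and TEAD list was called lower with the GC content and length trend removed (adjusted p = 0.015).

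Of 18 extracellular matrix genes 1 rose and 6 fell (1 and 6 adjusted over the list alone). The laminin chain gene Lamc1 fell from 165 and 180 to 102 and 106, the nidogen genes Nid1 and Nid2 from 36 and 40 to 20 and 21 and from 118 and 128 to 86 and 88, and Spp1, the gene of osteopontin, from 275 and 290 to 155 and 145 (log2 fold change -0.91, SE 0.05, adjusted p = 0.0157). Agrn and Fbln1 also fell and the protease gene Mmp2 rose. The camera test of the list gave an adjusted p of 0.196. It called the list lower with the GC content and length trend removed (0.0032) and with random decimals without WT 1 (0.025) or without Myh9 KO 2 (0.015). Of 23 cell junction genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.369). Cldn6 rose from 13 and 13 to 20 and 20, Ctnnb1, the gene of beta-catenin, fell from 316 and 314 to 268 and 268. Cgn (2 and 2, then 3 and 3) was not called with random decimals. Of 20 focal adhesion and integrin genes Itga5 rose from 38 and 40 to 50 and 49 and Itgb5 fell from 65 and 65 to 38 and 43. Adjusted over the list alone none of the 20 was called by limma (0 higher and 0 lower, 6 at an unadjusted p under 0.05), and the camera adjusted p was 0.773.

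**Figure D2:**
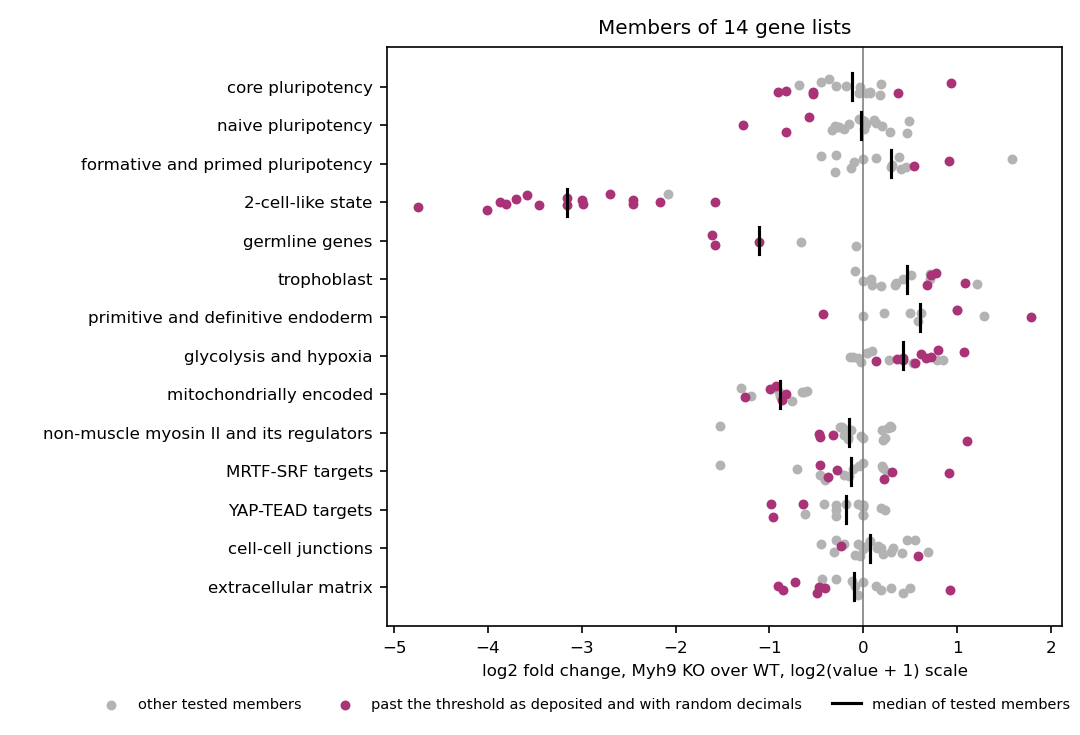
Log2 fold change of the tested members of 14 gene lists (x axis, log2(value + 1) scale, Myh9 KO over WT). Each point is a gene, coloured where both tests called it, and black lines mark list medians. The points of the 2-cell-like list lie to the left of 0, 15 of its 17 members being listed at 0 in both Myh9 KO libraries, and the pluripotency lists have medians of -0.12, -0.03 and 0.29.

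Of 21 tested members of the glycolysis and hypoxia list, 10 rose and 11 were not called (12 higher adjusted over the list alone). The list was higher by camera (adjusted p = 2.61e-05; adjusted p = 0.50 with an estimated correlation). Ldha, the gene of lactate dehydrogenase A, rose from 1054 and 1069 to 1853 and 1826 (log2 fold change 0.79, SE 0.01, limma adjusted p = 0.00201), Gapdh from 11967 and 11933 to 18286 and 18402 (0.62, SE 0.01, adjusted p = 0.00111), Tpi1 from 344 and 334 to 729 and 705 (1.08, SE 0.03, adjusted p = 0.00406) and the glucose transporter gene Slc2a3 from 625 and 641 to 999 and 1009 (0.66, SE 0.02, adjusted p = 0.00406). Pfkl, Slc2a1, Hk2, Pgam1, Pkm and Pgk1 rose as well. Aldoa (2047 and 2022, then 1966 and 2044) and the hypoxia-induced Vegfa (4 and 6, then 4 and 5) and Bnip3 (10 and 12, then 12 and 8) were not called. Of the 50-base words of Gapdh and Pgk1, 25.1% and 53.9% occur in other genes. Gapdh, Tpi1, Slc2a3 and Hk2 lie on chromosome 6, whose genes were higher as a group. Without chromosomes 6 and 8, 6 of 16 members were higher, the median was 0.21 and camera gave an adjusted p of 0.00082.

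Of 13 transcripts encoded by the mitochondrial genome 5 fell (11 adjusted over the list alone, and 13 with random decimals), and each of the 13 had a negative log2 fold change, with a median of -0.89, or -0.46 with the GC content and length trend removed. The list was lower by camera (adjusted p = 6.94e-05; adjusted p = 0.70 with an estimated correlation). The cytochrome oxidase subunit mt-Co1 fell from 4193 and 4178 to 2195 and 2022 (log2 fold change -0.99, SE 0.05, limma adjusted p = 0.0129), mt-Nd2 from 190 and 159 to 73 and 71, mt-Nd4 from 200 and 186 to 114 and 104 (a gene that overlaps mt-Nd4l, which fell too), and mt-Nd6 (a gene that overlaps mt-Nd5) from 431 and 409 to 244 and 217. Of the 50-base words of mt-Co1 and mt-Nd4, 51.1% and 62.2% occur in other genes. For mt-Atp6, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l the share was 98.0% to 100%, so these values are uncertain. It was 0% for mt-Nd6, mt-Nd1, mt-Cytb and mt-Atp8. The mitochondrial genome held 1.19% and 1.21% of the summed values in WT and 0.705% and 0.612% in Myh9 KO. Genes of low GC content were lower as a class, both between groups (median log2 fold change -0.19 for genes of 31.9% to 46.4% GC and 0.09 for genes of 56.4% to 76.3%) and between the Myh9 KO libraries (Myh9 KO 2 against Myh9 KO 1, -0.15 and 0.10), and the mitochondrial members have a GC content of 31.9% to 41.1%. Of 20 cholesterol synthesis genes 2 rose and 3 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.504), with Mvk (35 and 33 to 48 and 52) and Mvd higher and Cyp51 (20 and 21 to 14 and 14), Fdps and Fdft1 lower.

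Among 13 NODAL and BMP targets 2 were higher and 2 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.369). The BMP-responsive Id1 rose from 95 and 101 to 306 and 361 (log2 fold change 1.75, SE 0.11, limma adjusted p = 0.0178) and Id3 from 110 and 109 to 168 and 185. Smad7 fell from 35 and 37 to 24 and 26, and Bambi (3 and 3, then 2 and 2) was not called with random decimals. Among 9 WNT targets 2 were higher and 1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.582). Notum, a WNT inhibitor gene that overlaps the gene Notumos, fell from 47 and 48 to 14 and 16 (log2 fold change -1.60, SE 0.08), and Cdx1 rose from 53 and 48 to 90 and 101. Tcf7 (33 and 32, then 39 and 39) was not called with random decimals. Of 12 FGF and ERK feedback genes Spry4 rose from 13 and 15 to 25 and 24 and Etv5 fell from 274 and 280 to 233 and 237 (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.664). Of 11 LIF and STAT3 targets limma called 0 (0 adjusted over the list alone, 4 higher with random decimals, 3 at an unadjusted p under 0.05, camera adjusted p = 0.186). Sgk1 lay at 190 and 207 and at 256 and 260 and Myc at 26 and 26 and at 36 and 41.

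Of 17 p53 targets 2 were lower (2 adjusted over the list alone), namely Aen (87 and 91 to 65 and 64), which fell, and Mdm2 (28 and 28, then 23 and 22), which was not called with random decimals. The camera adjusted p of this list was 0.157. The list was called lower with random decimals (0.0396), with the GC content and length trend removed (0.015) and without Myh9 KO 2 (0.031). Of 12 immediate early and heat shock genes 2 were lower (2 adjusted over the list alone, camera adjusted p = 0.504): Dusp1 fell from 36 and 36 to 23 and 24, and Jun (4 and 4, then 3 and 3) was not called with random decimals. Of 15 genes of the integrated stress and unfolded protein response, Atf5 fell from 81 and 81 to 42 and 45, 2 were higher and 4 lower adjusted over the list alone, and camera gave an adjusted p of 0.212, and 0.018 (lower) with the GC content and length trend removed. Of 18 mitosis and cytokinesis genes 1 was higher and none was called adjusted over the list alone (0 higher and 0 lower by limma, 5 at an unadjusted p under 0.05, camera adjusted p = 0.626). This was Birc5 (306 and 302, then 329 and 332), which was not called with random decimals. Of 12 interferon response genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), with Bst2 up from 68 and 79 to 144 and 157 and Ifitm1, Ifitm3 and Oas1a (57.6% of its 50-base words occur in other genes) down, Ifitm3 from 447 and 423 to 217 and 223. The median of that list was 0.10, its mean -0.10 and its camera direction down (adjusted p = 0.753).

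Of 25 tested imprinted genes 6 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.226). Mest rose from 102 and 100 to 200 and 194 (log2 fold change 0.96, SE 0.02), Peg10 from 23 and 23 to 49 and 51, H19 from 43 and 40 to 72 and 77 and Phlda2 from 13 and 12 to 24 and 23. Grb10 fell from 17 and 19 to 5 and 5 (log2 fold change -1.66, SE 0.07, limma adjusted p = 0.0088). Igf2 and Snrpn also rose. Mest, which overlaps Copg2, and Peg10 lie on chromosome 6. Of the sex chromosome checks only Eif2s3y reached the filter (5 and 5, then 1 and 0; 0 called over all genes, 1 lower adjusted over the list alone, limma adjusted p = 0.0992). Ddx3y, Kdm5d and Uty were listed at 0 in every library. Erdr1, also listed on chromosome Y, fell as given above. Uba1y on chromosome Y, chosen after its values were seen, went from 4 and 5 to a listed 0. Chromosome Y was not part of the chromosome medians or tests below.

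Genes of chromosomes 6 and 8 were higher in Myh9 KO as whole groups. Over 397 genes of chromosome 6 with a mean value of at least 5 the median log2 fold change was 0.46 and 90.7% were above 0, and over 522 genes of chromosome 8 the median was 0.21 and 77.6% were above 0. Each Myh9 KO library showed it, with chromosome 6 medians of 0.50 and 0.46 and chromosome 8 medians of 0.20 and 0.22 against the WT mean. Library medians of the other 18 chromosomes ran from -0.18 on chromosome 18 in Myh9 KO 2 to 0.03 on chromosome 17 in Myh9 KO 2. In a camera test over chromosomes with the preset correlation, added after the data were seen, both were higher (adjusted p = 1.22e-19 for chromosome 6 and 4.66e-08 for chromosome 8). With an estimated correlation, of 0.0319 and 0.0353, the camera adjusted p was 0.612 and 0.811. With the preset correlation camera also called chromosomes 13 (median -0.14, 29.5% of genes above 0, adjusted p = 0.0105) and 18 (median -0.15, 24.2% above 0, adjusted p = 0.0167) lower, each with an adjusted p of 0.966 with an estimated correlation. With the GC content and length trend removed the medians were -0.06 for chromosome 13 and -0.09 for chromosome 18, against 0.51 for chromosome 6 and 0.19 for chromosome 8. Chromosomes 6 and 8 held 10.7% of tested genes and 35.3% of the genes called higher by the designed test, 186 on chromosome 6 and 98 on chromosome 8. Of the genes called higher by both tests they held 43.5%, 169 on chromosome 6 and 81 on chromosome 8. Nanog, Gdf3, Dppa3, Peg10, Mest, Zyx and Pianp are on chromosome 6, and Cdh1, Zfp42, Col4a1, Mmp2, Bst2, Mt3 and Mt4 on chromosome 8. Without both chromosomes 487 genes were higher and 812 lower.

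**Figure D3:**
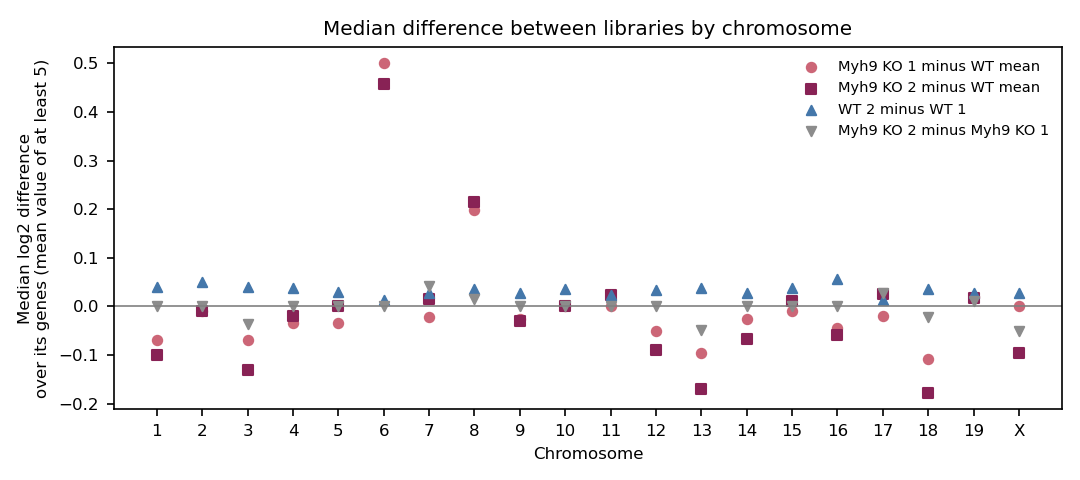
Median log2 difference over the genes of each chromosome with a mean value of at least 5, for each Myh9 KO library against the WT mean and for the replicates of each group against each other. Chromosome 6 (0.50 and 0.46) and chromosome 8 (0.20 and 0.22) stand above 0 in both Myh9 KO libraries, and their replicate differences lie between 0.00 and 0.04.

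Camera in limma called 6 of 29 lists, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 7 with random decimals and 16 by fry, which does not compare a list with other genes. Groups of 2 libraries leave few degrees of freedom, and 573 of the 1699 designed calls had equal whole numbers in the replicates of both groups, of which 177 were also called with random decimals.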

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

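Random decimals, other scalings, removal of the GC content and length trend and the fit without chromosomes 6 and 8 were chosen after seeing the data. Genes higher and lower numbered 805 and 894. They numbered 10 and 44 with the replicate number as a block, 65 and 139 with a tested minimum change of 1.5-fold, 248 and 300 at an adjusted p under 0.01, 1242 and 1345 with random decimals, and 1230 and 1459 with random decimals and without Myh9 KO 1. With random decimals they were 611 and 642 without WT 1, 716 and 611 without WT 2 and 937 and 1105 without Myh9 KO 2, so leaving out either WT library moved them by over 1.5 times. Without chromosomes 6 and 8, 487 were higher, and with the GC content trend removed 1397 were lower. The other settings moved neither count by over 1.5 times, and leaving out 1 library gave 591 to 1026 higher and 731 to 1008 lower. Of the calls of the designed test, between 333 and 451 of the higher and between 428 and 462 of the lower genes were shared with those fits.

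The labels do not say that the replicate numbers pair the libraries. The deviations of same-numbered libraries had r = 0.0407 across genes. With 2 pairs, and genes that are not independent replicates, this cannot show whether the libraries were paired. With the block, which leaves 1 residual degree of freedom, Myh9 kept its log2 fold change of -3.203 at an adjusted p of 0.0723. Without single libraries its log2 fold change lay between -3.336 and -3.07. Of 101 named genes called, 5 were called with the block, 27 with the minimum change, 41 at an adjusted p under 0.01, 42 to 56 without single libraries and 76 to 88 when random decimals were added to that. Pou5f1, which was not called, turned from 0.03 to -0.0009003 with upper-quartile scaling and to -0.01459 with the GC content trend removed. With that trend removed, 579 of the 805 genes called higher and 639 of the 894 called lower in the designed test kept their call. Another 5 genes called in the designed test, none of them a named gene, changed the sign of their log2 fold change. No other setting did this to a called gene.

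Of 29 lists, 6 passed as designed, 0 with an estimated correlation, 16 by fry and 10 with the GC content trend removed. With an estimated correlation the adjusted p was 0.5 for the 2-cell-like, trophoblast and glycolysis lists and 0.7 for the endoderm, germline and mitochondrial lists. That setting leaves camera few degrees of freedom here, so a failure there alone decides little. The estimated correlation was 0.471 for the mitochondrial, 0.189 for the germline and 0.135 for the 2-cell-like list, against the preset 0.01. For these lists the p-values with the preset correlation may be too small. It was 0.0196 for the glycolysis, 0.0179 for the endoderm and -0.0197 for the trophoblast list. The core pluripotency list passed by fry as lower (0.01). The endoderm list was lost with the stricter filter (0.38), without chromosomes 6 and 8 (0.096) and with random decimals without WT 1 (0.067), Myh9 KO 1 (0.073) or Myh9 KO 2 (0.15), and without single libraries it ranged from 0.035 to 0.27. The cause was not tested. The germline list had under 5 tested members without either WT library, with the stricter filter and with median-of-ratios scaling, so it has no value there. Tests that need read counts (DESeq2, limma-voom and factors inside edgeR) were not run, and depth is unknown.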

Other observations

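The single genes and the groups taken by gene symbol in the next paragraphs, the nuclear respiratory chain genes, every test on chromosomes 6 and 8, the sum over the Zscan4 family and the test of GC content as a part of the mitochondrial change were chosen after the result was seen.

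Several genes outside the lists changed strongly. Rpl39l, a ribosomal protein paralog, fell from 235 and 266 to 30 and 29 (log2 fold change -3.04), Pttg1, the gene of securin, from 137 and 125 to 21 and 16 (-2.77), and the carbonyl reductase gene Cbr3 from 48 and 51 to 11 and 10 (-2.14). Zp3 fell from 29 and 29 to 12 and 12 and Ooep from 62 and 57 to 27 and 30. Trh, the gene of thyrotropin-releasing hormone, rose from 214 and 226 to 712 and 744 (log2 fold change 1.72) and Tmsb10, of a thymosin, from 5910 and 5535 to 10259 and 10632, both on chromosome 6. Upp1, of a uridine phosphorylase, rose from 437 and 450 to 894 and 891. Uba1y on chromosome Y went from 4 and 5 to a listed 0 in both Myh9 KO libraries.

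Groups taken by gene symbol moved both ways. Of 18 glutathione S-transferase genes 3 rose and 4 fell, among the latter Gstm1 (144 and 143 to 68 and 68) and Gsto1 (113 and 111 to 48 and 56), with a median of -0.07. Of 6 glutathione peroxidase genes 2 were higher and 1 lower by the designed test, and 1 and 1 by both tests. Of 4 metallothionein genes Mt3 and Mt4, which had low values, rose and Mt2 fell (2480 and 2363 to 1421 and 1368). Mt1 (1382 and 1253, then 892 and 944) was not called by the designed test (limma adjusted p = 0.0537). With random decimals it was called lower (limma adjusted p = 0.000502). Of 75 ribosomal protein genes 3 were higher and 11 lower by the designed test and 3 and 10 by both tests, with a median of -0.11.

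Genes of chromosome 6 (median log2 fold change 0.46) and chromosome 8 (0.21) were higher in Myh9 KO. With the trend on GC content and transcript length removed the medians were 0.5078 and 0.1927, which argues against that bias as the whole cause. All 11 windows of 10 Mb with at least 10 genes on chromosome 6 had a median above 0, from 0.3035 to 0.6484. This argues against a few genes or a single segment there. All 12 such windows on chromosome 8 had a median above 0 too, but unevenly, from 0.07378 to 0.3178. Windows of other chromosomes were not computed, so a segment of chromosome 8 with a larger shift is not excluded. The larger of the medians of the Myh9 KO libraries was 0.5 for chromosome 6 and 0.2152 for chromosome 8, below the 0.585 of 3 copies over 2, so an extra copy of each in all or part of the Myh9 KO cells is a candidate explanation that stays open. No DNA was measured, and whether a gain would go with the loss of Myh9 or with the clone was not tested.

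The 2-cell-like genes were lower in Myh9 KO. For the Zscan4 genes, reads moved between near-identical copies are argued against by the sum over the family, which in Myh9 KO was 1.376% of that in WT. Other members with shared 50-base words, such as Usp17lc (44.7%) and Pramef25 (63.6%), were not summed over their copies, so the sum does not cover them. The Zscan4 test took the place of an earlier one on members with under 10% shared 50-base words, which only Tmem92 met (1.93% shared, 22 and 20 to 1 and 1). A GC content and length bias is argued against by a corrected median of -2.993, which holds genes at 0 and is no measure of size. A smaller share of 2-cell-like cells in the Myh9 KO culture may account for the fall, but only 2 members reached a value of 1 in both Myh9 KO libraries, so it cannot be told apart from lower expression in each such cell.

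Mitochondrially encoded transcripts were lower in Myh9 KO, with log2 fold changes from -1.30 to -0.60. The 172 nuclear genes of the same GC content had a median of -0.273, above every mitochondrial member, which argues against a GC content trend between the libraries as the whole cause. That median lies below 0, and with the trend removed the mitochondrial median went from -0.89 to -0.4606, so the trend may be a part of the cause. Of 89 nuclear genes of the respiratory chain, taken by symbol, 5 were higher and 7 lower with a median of -0.05. A change in mitochondrial content or transcription in Myh9 KO cells stays open and was not tested.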
